A study of Mus musculus with 2 samples.

How the data were processed

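The series held 1 ChIP-seq library for MTF2 and 1 for JARID2, each from mouse ES cells, with no replicate, no input and no control antibody among the samples. Per the labels' protocols, the libraries were amplified with 15 PCR cycles and sequenced on a Genome Analyzer. The deposited files listed aligned reads as genomic intervals, 1 line per read. The aligner, its settings, the genome build and any removal of repeat reads are not given in the sources used here. The deposited MTF2 file held 10986401 reads of 52 bp and the deposited JARID2 file 14465269 reads of 36 bp. Each line also carried a deposited score, which ran from 0 to 10 in MTF2, with 39.3% of reads at 0, and was 1000 on every line of JARID2. The meaning of that score is not given, and it was used only for 1 alternative. The JARID2 file had no line on chromosome Y or on the mitochondrial chromosome.

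Coordinates are printed as the files give them, counted from 1. The highest coordinates per chromosome lie within the chromosome lengths of the mouse build NCBI 36 as recalled, which is an inference from the values and not a statement of the authors. The gene table at hand was of the assembly GRCm38.p6, and on 11 of 20 chromosomes its genes ran past the highest read, so the builds differ. None of its coordinates was used. It served only for the number of protein-coding genes per chromosome and for the chromosomes that carry the Hox clusters. Promoter enrichment, the 14 gene lists (cell type markers among them), the genes Jarid2 and Mtf2, annotation of regions and base composition had been planned and were not analysed here, because they need an annotation or genome of the files' own build. Regions are named by position instead, as planned for that case.

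Reads with the same chromosome, strand and 5' end were kept once. This left 8946204 reads for MTF2 (81.4%) and 12900993 for JARID2 (89.2%). Repeat reads from PCR are not independent molecules, and all intervals and floors given here cover counting error only. The fragment length was the distance between 100 and 400 bp, in steps of 10 bp, with the most pairs of opposite-strand 5' ends. It was 140 bp for MTF2 and 200 bp for JARID2, and each read was moved by 50% of it. Reads were counted in 1 kb bins on chromosomes 1 to 19, X and Y, of which 2539671 held at least 1 read in either library. The expected count of a chromosome was the mean over its bins up to the 99th percentile, with an autosomal median of 3.39 reads for MTF2 and 4.25 for JARID2. A bin was called enriched with a Poisson upper-tail p, Benjamini-Hochberg adjusted over all bins, of at most 0.001, a count of at least 5 times expected, and at most 90% of its reads on 1 strand. Called bins at most 1 kb apart were merged. The Poisson test compares bins of 1 library with each other and says nothing of replicates.

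Overlap was counted as a shared bin, beside 100 random placements of the regions on their own chromosomes and beside the number that independent bins would share. Ratios of JARID2 to MTF2 used reads divided by the kept reads of the library over the union of both lists, and a region was called skewed at 4-fold or more from the median ratio with at least 20 reads in the higher library. Shares and ratios have exact Clopper-Pearson intervals and folds exact Poisson intervals at 95%, and medians have order-statistic intervals. A fold against 0 reads was computed against a floor of 3 reads. The rule for skewed regions did not use that floor. Highest steps were taken in 200 bp steps. Differences between MTF2 and JARID2 are differences between these libraries and were not tested between the factors.

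The caller was tested on simulated counts over the same 2539671 bins, with 200 bins raised per fold size. With the spread of the uncalled bins added to the background, it called 79.5% of the bins raised 6-fold and 98.5% of those raised 8-fold for MTF2. For JARID2 those shares were 79.0% and 97.5%. It also called 114 bins that had not been raised for MTF2 and 2073 for JARID2. With the spread of all bins up to the 99th percentile, which still include some called bins, the latter numbers were 43 and 9984. No unraised bin was called in either library when the background had Poisson spread alone. The Poisson p therefore does not hold its nominal error rate in JARID2 if that spread is background. A negative binomial tail was added as an alternative after this was seen. With the spread of the uncalled bins, that tail called 1 unraised bin in each library. It called 32.5% and 83.0% of the MTF2 bins raised 6-fold and 8-fold, and 1.5% and 15.5% of such JARID2 bins.

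The rule for named regions, written for promoters with regions as the stated substitute, took the 10 highest MTF2 folds, the 10 highest JARID2 folds, and the 5 highest and 5 lowest ratios, at most 1 per 100 kb. The lists of widest regions and of evenly spaced regions, the breakdowns by JARID2 width, rank and fold, and the chromosome Y exclusion were chosen after the data were seen. So was the term pile-up, which is used for bins with at least 3 deposited reads per kept read in either library. The other settings, fixed before the data were examined, covered repeat reads, thresholds, local background, bin size, strand rule, depth, overlap fraction, pseudocount, low-count filter, scaling, background subtraction, ratio size and merging distance. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and random steps used the seed 1.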

Results

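The occupancy of MTF2 and JARID2 was profiled in mouse embryonic stem (ES) cells by ChIP-seq, in which DNA bound by a protein is recovered with an antibody and sequenced. MTF2 is a Polycomb-like protein and JARID2 a Jumonji-family protein, and both are partners of PRC2, a complex that places repressive methyl marks on histones. The cells came from a 129SvJae by C57BL/6 background, were used at passages 10 to 15 and had been kept off feeder cells for 2 to 3 passages. There was 1 library per factor and no replicate or input, so enrichment was set against the rest of the same library. The MTF2 library held 8946204 distinct reads and the JARID2 library 12900993. The series title names JARID2 and PRC2 as partners, and the design implies the question of whether the factors occupy the same places.

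JARID2 reads were concentrated in far more places than MTF2 reads. JARID2 was enriched in 27525 regions that took 25.01% of its reads (95% interval 24.98 to 25.03), and MTF2 in 2008 regions that took 2.18% (2.18 to 2.19). The median fold over the expected count was 8.33 in JARID2 regions and 6.42 in MTF2 regions. Folds of at least 20 occurred in 3039 JARID2 regions and 41 MTF2 regions. Regions at least 10 kb wide numbered 291 for JARID2 and 93 for MTF2, and the narrowest class of 1 kb held 63.2% and 60.2% of the lists. These counts depend on the caller. A stricter rule left 12113 JARID2 and 562 MTF2 regions, and a negative binomial tail left 18091 and 1290. In the simulations that tail called only 15.5% of JARID2 bins raised 8-fold, so regions it lost need not be false calls.

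Most MTF2 regions overlapped JARID2 regions, while few JARID2 regions had an MTF2 region. Of the 2008 MTF2 regions, 1329 overlapped a JARID2 region (66.2%, 64.1 to 68.3), against a mean of 72.5 and a maximum of 94 in 100 random placements. Without an input, random placement cannot separate shared binding from places raised in both libraries for other reasons. Of the overlapping MTF2 regions, 207 had a JARID2 fold of 0.5 to 1 times the MTF2 fold, and 217 of 1 to 2 times. It was 2 to 4 times in 284, 4 to 8 times in 363, 8 times or more in 235, and lower than 0.5 times in the rest. Of the JARID2 regions, 1148 overlapped an MTF2 region (4.17%, 3.94 to 4.41). That share depended on the processing. It was 2.82% under the stricter rule, 1.53% with MTF2 reads of score 0 alone and 4.42% with the negative binomial tail. Both libraries were called in 3405 bins, 37.0 times the 92.1 that independent bins would share. Overlap rose with JARID2 fold, from 4.17% of all regions to 31.6% of the 2008 highest and 55.6% (51.1 to 60.01) of the 500 highest.

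Wide JARID2 regions were mostly shared. Only 171 of 17407 JARID2 regions of 1 kb overlapped an MTF2 region (0.982%, 0.841 to 1.14). The share was 4.88% at 2 to 4 kb, 32.8% (29.9 to 35.9) at 5 to 9 kb, 75.6% (69.7 to 80.9) at 10 to 19 kb and 91.8% (80.4 to 97.7), or 45 of 49 regions, from 20 kb upwards. With the negative binomial tail the same order held, from 1.11% at 1 kb to 88.2% (63.6 to 98.5) of 17 regions from 20 kb upwards. A wider region also offers more bins to overlap, and no correction was made for that.

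**Figure D1:**
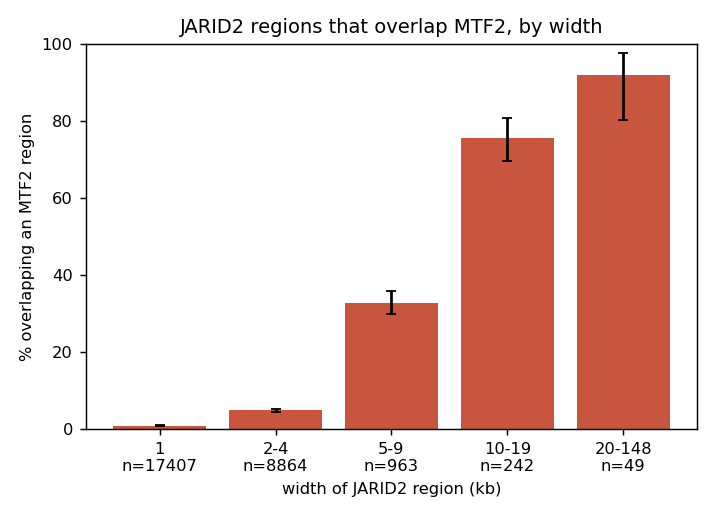
Share of JARID2 regions that overlapped an MTF2 region (vertical axis, percent) by the width of the JARID2 region in kb (horizontal axis). Bars are shares, error bars exact 95% binomial intervals for counting error, and n is the number of regions. The share rose from 0.982% at 1 kb to 91.8% from 20 kb upwards.

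Among the widest shared regions, 4 blocks of 53 to 73 kb were raised on average in both libraries, with JARID2 several times further above its background. They were selected, after the data were seen, as the widest with a JARID2 fold at least 2 times the MTF2 fold and at least 50% of their bins called in MTF2. MTF2 was uneven within them. On chromosome 2 it was 0.872-fold in the bin from 74456001 and 1.16-fold in that from 74483001, where JARID2 was 52.2 and 132-fold. On chromosome 15, from 102775001 to 102848000, MTF2 was 6.65-fold (6.33 to 6.99) and JARID2 29.9-fold (29.2 to 30.5) over expected. On chromosome 2, from 74455001 to 74518000, the folds were 7.19 (6.84 to 7.56) and 39.5 (38.8 to 40.3). On chromosome 6, from 52127001 to 52185000, they were 7.13 (6.77 to 7.51) and 51.5 (50.6 to 52.4). On chromosome 11, from 96085001 to 96138000, they were 5.82 (5.46 to 6.19) and 28.6 (27.9 to 29.2). The next widest by the same selection were 43 kb on chromosome 6 from 47666001, 37 kb on chromosome 6 from 47580001 and 35 kb on chromosome X from 165319001, with MTF2 at 10.9, 12.1 and 16.2-fold and JARID2 at 96.9, 109.9 and 55.3-fold. The regions on chromosome 6 from 47666001 and 47580001 had evenly spaced JARID2 peaks. Further shared regions of 22 kb lay on chromosome 2 from 71326001, on chromosome 17 from 85516001 and on chromosome 19 from 43652001, with MTF2 at 7.36, 7.28 and 5.91-fold and JARID2 at 52.7, 44.2 and 35.7-fold. The depth-scaled ratio of JARID2 to MTF2 reads in the 4 widest ran from 3.90 (3.70 to 4.11) to 5.61 (5.25 to 6.00).

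**Figure D2:**
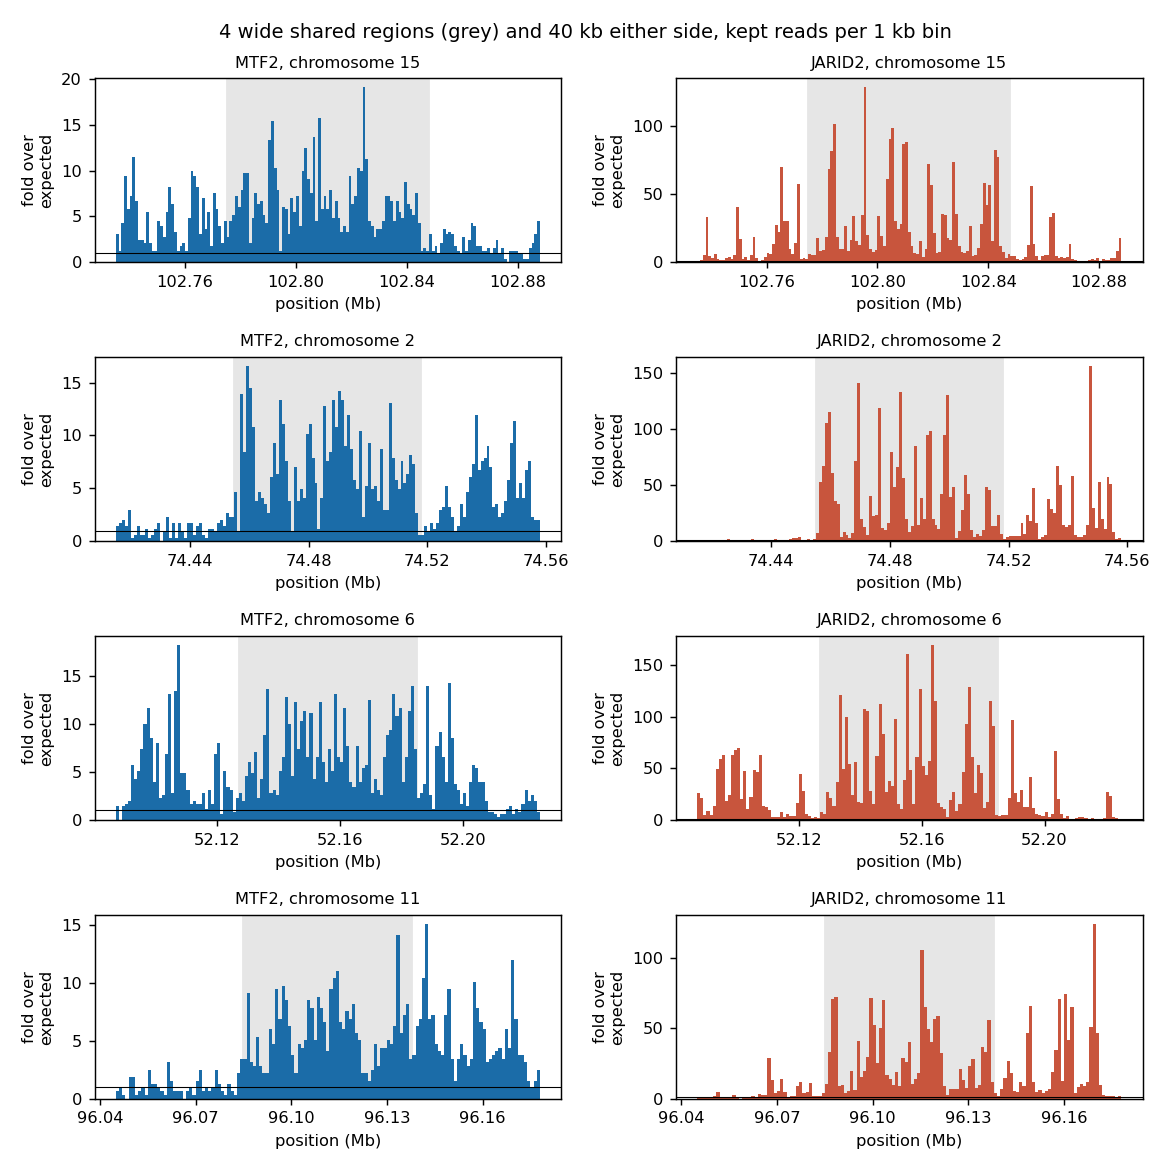
Fold over expected reads per 1 kb bin (vertical axes, each panel with its own scale) along position in Mb (horizontal axes) for MTF2 (left, blue) and JARID2 (right, red) in the 4 wide shared regions, shaded grey, with 40 kb on either side. The line marks 1-fold. MTF2 averaged 5.82 to 7.19-fold over the shaded regions and JARID2 28.6 to 51.5-fold.

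The MTF2 level rose with the JARID2 level in bins where JARID2 was 20-fold or more. In 1 kb bins with JARID2 at 5 to 10-fold the median MTF2 level was 0.593-fold, and 17.1% of those bins had no MTF2 read. At 20 to 50-fold JARID2 the median was 1.67, at 50 to 100-fold 2.92 and at 100-fold or more 4.11, or 3.79 with pile-up bins left out. The mean MTF2 level at 5 to 10-fold was 1.05 (1.05 to 1.06), so some bins of that class held many MTF2 reads. Bins with JARID2 below 0.5-fold had a median of 0.911. Across all mappable bins Pearson's r of the log2 levels was -0.0606 and Spearman's rho -0.0787, and across the 49297 bins called in either library they were 0.218 and 0.150. These correlations are across bins, which are not independent replicates.

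**Figure D3:**
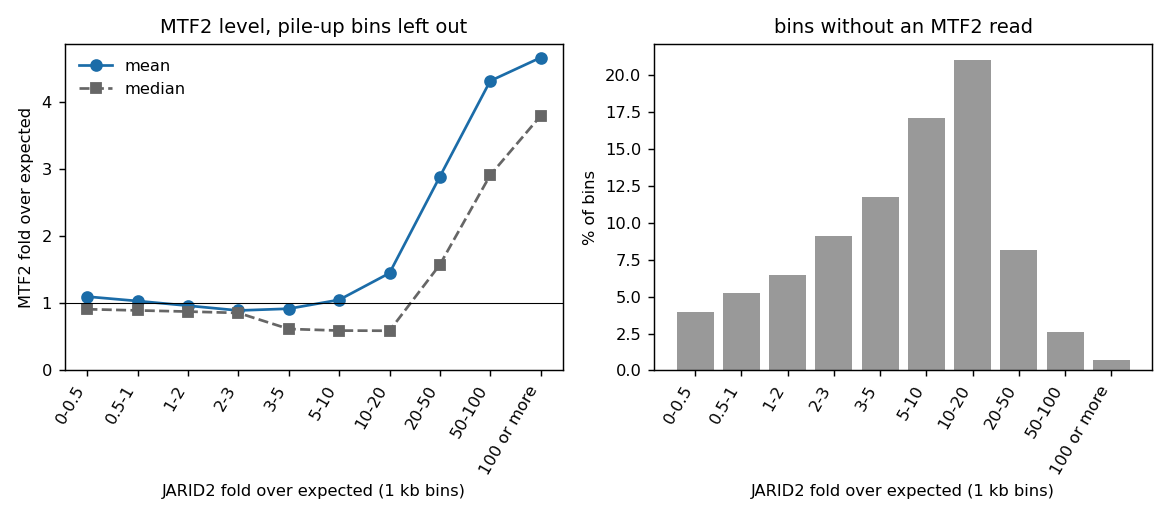
MTF2 fold over expected with pile-up bins left out (left, mean as circles and median as squares) and percent of all bins without an MTF2 read (right, bars), both by the JARID2 fold of the 1 kb bin (horizontal axes). The median rose from 0.593 at 5 to 10-fold JARID2 to 3.79 at 100-fold or more, and bins without an MTF2 read peaked at 21.1% for 10 to 20-fold.

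Over the 27983 regions of both lists together, the median depth-scaled ratio of JARID2 to MTF2 reads was 13.0 (12.8 to 13.2). It was 4.54 (4.23 to 4.86) in the 1187 regions called in both libraries, 14.1 (13.9 to 14.3) in the 26249 called in JARID2 alone and 0.184 (0.162 to 0.201) in the 528 called in MTF2 alone outside chromosome Y. The 4-fold rule, set around that median, marked 4337 regions as JARID2-skewed. Of these, 3745 had no MTF2 read and met the rule with any JARID2 count of at least 20, because their ratio has no finite value. On a floor of 3 reads many of them lie below the cut of 51.97, and many below the median. The 5 highest, at most 1 per 100 kb, ran only from 72.8 down to 58.9 on that floor. In the first part of chromosome 1, all such regions lay below the cut and most below the median. The share over all chromosomes is not given here. Only in the other JARID2-skewed regions was a ratio of at least 51.97 measured. The rule marked 1585 with a ratio of at most 3.25 as MTF2-skewed, which includes regions with more JARID2 than MTF2 reads after scaling. The regions with the highest ratio had 0 MTF2 reads, and their folds were computed against the floor of 3 reads. On that floor JARID2 was 72.8-fold higher on chromosome 8 from 125437001 to 125438000. It was 67.4-fold higher on chromosome 15 from 82087001 to 82088000 and 63.8-fold higher on chromosome 16 from 11337001 to 11338000. The floor values were 63.3 on chromosome 5 from 120363001 and 58.9 on chromosome 7 from 44178001. The exact 95% intervals of these ratios reached lower, to 58.8, 54.5, 51.5, 51.1 and 47.6 in the same order. The 3 lowest ratios lay on chromosome Y, where the JARID2 file had no line, and carry no comparison. Elsewhere, on the same floor, MTF2 was 13.5-fold higher on chromosome 9 from 10666001 to 10667000 (28 reads against 0). It was 11.5-fold higher on chromosome 16 from 87398001 to 87399000 (24 against 0). The exact 95% intervals of these MTF2 to JARID2 ratios reached down to 10.2 and 8.69.

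Shared JARID2 regions were wider than the rest. JARID2 regions that overlapped MTF2 had a median width of 4 kb (4 to 5) and the other JARID2 regions 1 kb. The highest 200 bp steps of the factors lay a median of 800 bp apart in the 1148 shared regions, and within 1000 bp in 60.7% (57.8 to 63.6). With the MTF2 step placed at random in the same regions, a comparison added after the data were seen, the mean of 100 medians was 1192 bp (1000 to 1200) and the share within 1000 bp averaged 47.8% (45.4 to 51.5). Around the JARID2 highest step of 1105 shared regions outside pile-up bins, the median JARID2 level fell from 102-fold at the step to 9.43-fold 1000 bp upstream and 9.51-fold 1000 bp downstream in coordinate order. The MTF2 median had no peak at that step, with 4.33-fold at the step and 4.28 and 4.33-fold at those distances. The MTF2 mean was highest at the step, at 7.96-fold. It was 6.46 and 6.72-fold 200 bp upstream and downstream, and 5.58 and 5.46-fold at 1000 bp. With 3.39 MTF2 reads expected per 1 kb bin, the median over 200 bp steps is coarse and could hide a peak. The step was chosen for its JARID2 height, which raises the JARID2 value there and not the MTF2 value.

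Of the 10 highest MTF2 folds, 7 lay in regions with at least 3 deposited reads per kept read in both libraries and 3 in regions below that level in both. Of the 10 highest JARID2 folds, 4 lay in regions at that level in both libraries, 5 in JARID2 alone and 1 in neither. The region of 39 kb on chromosome 9 from 3000001 to 3039000 reached 327-fold in MTF2 and 203-fold in JARID2, and the region of 3 kb on chromosome 5 from 3000001 to 3003000 reached 333 and 208-fold. On chromosome 2 from 98463001 to 98469000 the folds were 191 and 156, with 107 deposited MTF2 reads per kept read, and on chromosome 14 from 39187001 to 39188000 they were 180 and 169. Chromosome 14 from 18208001 had 160 and 118-fold, chromosome 10 from 7229001 had 119 and 67.4-fold and chromosome 9 from 35054001 had 100 and 77.3-fold. The list of the 10 highest MTF2 folds closed with chromosome 6 from 103614001 (80.5-fold), chromosome X from 72851001 (70.6-fold) and chromosome 1 from 24565001 (69.6-fold). The 3 without such repeats were those on chromosomes 10, X and 1. In all 10 the MTF2 fold exceeded the JARID2 fold. The highest JARID2 fold was 360.0 (353 to 367) on chromosome 17 from 39451001 to 39457000, where MTF2 was 45.4-fold. Next came chromosome X from 165433001 (252-fold) and from 165556001 (241-fold) and chromosome 18 from 90736001 (217-fold). The last 2 of these hold the highest coordinate of any read on their chromosomes, 165556469 and 90736837. Chromosome 4 from 118044001 to 118047000 reached 183-fold in JARID2 and 19.8-fold in MTF2. The 1 of these 10 below the repeat level in both libraries was chromosome 15 from 91734001 to 91739000. JARID2 was at 158-fold (153 to 164) there and MTF2 at 4.98-fold (3.96 to 6.18), with 1.45 deposited JARID2 reads per kept read. Other shared regions below that level followed closely in JARID2 fold. They lay on chromosome 17 from 13343001 (155-fold), chromosome 16 from 11057001 (155-fold) and chromosome 8 from 126423001 (152-fold). Repeated sequence was not examined in any of these, since no genome of the files' build was used.

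Background levels differed between chromosomes. Relative to the median autosome, chromosome 8 had 1.36 times the expected MTF2 reads and 1.37 times the expected JARID2 reads, the highest autosome in both libraries. Chromosome X had 0.660 times the MTF2 and 0.495 times the JARID2 level. MTF2 regions were denser on chromosome X, at 2.01 per Mb, than on any autosome (0.442 to 1.39), while JARID2 regions on X, at 11.4 per Mb, lay within the autosomal range of 8.84 to 13.7. The expected count per bin on X was 2.24 for MTF2 against an autosomal median of 3.39, and 2.10 for JARID2 against 4.25.

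**Figure D4:**
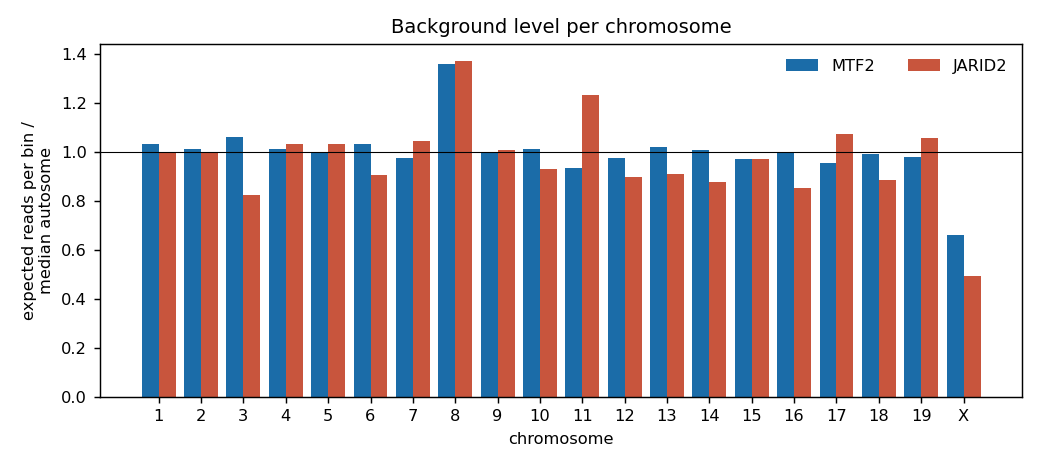
Expected reads per 1 kb bin relative to the median autosome (vertical axis) for each chromosome (horizontal axis), with MTF2 in blue and JARID2 in red. Chromosome 8 stood at 1.36 and 1.37 and chromosome X at 0.660 and 0.495.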

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

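The tests of depth thinning and of both libraries' chromosome 8 windows had their criteria set before their results were seen. The tests of base composition, of the MTF2 windows alone, of gene density and of an extra copy were chosen only after the results they concern had been seen. Outside the main measurement, the MTF2 library held 6528 kept reads out of 8019 deposited ones on the mitochondrial chromosome. No expected count was estimated for that chromosome, so these reads are not a measured enrichment. The JARID2 file had no line there, so no comparison was made.

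Bins with JARID2 at 5 to 20-fold held fewer MTF2 reads than background at the median. In 39270 such bins the median MTF2 level was 0.593, against 0.890 in bins called in neither library, while the mean of 1.17 was above background. The median stayed at 0.593 after JARID2 was thinned to the MTF2 depth, with 40077 bins in the class. Thinning left the MTF2 counts unchanged, and folds are relative to each library's own expected count. The test thus had little room to move the median and does not decide on the greater JARID2 depth as the cause. With 3.39 MTF2 reads expected per bin, the median also moves only in coarse steps. A candidate explanation is base composition bias in opposite directions, because the MTF2 level also fell with the JARID2 level in uncalled bins, to 0.844 times (0.840 to 0.847) between 0.5 to 1-fold and 2 to 5-fold JARID2, or 0.794 times from bins below 0.5-fold, a baseline dropped because leaving out empty bins raises it. JARID2 sites without MTF2 remain open as a biological explanation, untested, and base composition itself was not analysed here.

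Chromosome 8 carried more background than any other autosome in both libraries, 1.36 times the median of the others in MTF2 and 1.39 times in JARID2. Composition, read from gene density, is argued against as the cause, since chromosome 8 exceeded the level it predicts by 0.360 in MTF2 and 0.418 in JARID2, or 14.5 and 6.92 SD of the other autosomes. A local fault of the assembly is argued against in MTF2, where 96% of the 5 Mb windows lay above the median window of the other autosomes, but with 72% in JARID2 it cannot be told apart there, because JARID2 windows vary widely. A candidate explanation is an extra copy of chromosome 8 in part of the cells. It needs a level between those of 2 and 3 copies in both libraries, and the lower level found was 1.36. The next highest autosome was chromosome 3 in MTF2, at 1.06, and chromosome 11 in JARID2, at 1.25. The JARID2 level alone thus does not single out chromosome 8. Not every window was raised. In MTF2 those from 120000001 and 125000001 stood at 0.965 and 1.09, against a chromosome 8 median of 1.41. The extra copy is a hypothesis from the same data, and no karyotype was used here. No biological explanation was tested because the groups are antibodies.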

How the results depend on the processing

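The pile-up, score 0, 3-fold, negative binomial and chromosome Y alternatives were chosen only after the data were seen, and the others were planned. Over 14 results, 83 values under alternatives were computed: 55 stayed within 1.5 times (counts) or within the counting interval (other values), 28 moved and 0 reversed, and the cause was not tested except where the setting itself removes bins or reads. At an adjusted p of 1e-05 and 10-fold there were 562 MTF2 and 12113 JARID2 regions, with overlaps of 74.6% and 2.82%. Local background gave 973 and 16499 regions. The negative binomial tail gave 1290 and 18091 regions, overlaps of 72.7% and 4.42%, called-bin correlations of 0.273 (Pearson) and 0.251 (Spearman) and a median ratio of 17.8; it kept 50.3% of the JARID2 regions of 1 kb and 100% of those from 20 kb. MTF2 reads with score 0 alone gave 823 MTF2 regions and overlaps of 69.5% and 1.53%, and the 3-fold threshold overlaps of 63.0% and 3.51%. Counting all deposited reads gave an MTF2 overlap of 63.9% and a median ratio of 14.9, and scaling to reads outside called bins a ratio of 16.7. A pseudocount of 5 reads gave Pearson correlations of -0.0129 over all and 0.259 over called bins, pile-up removal 0.197 over called bins, and bins with at least 5 reads -0.322 (Pearson) and -0.384 (Spearman) over all bins, a filter on the sum that itself lowers a correlation. At 2-fold from the median, 7104 regions were JARID2-skewed and 5664 MTF2-skewed. Subtracting the expected background gave no value, because MTF2 was at or below it in 70.5% of the regions, and 8 of the 25 settings fixed beforehand, on promoters, gene lists and annotation, were not run. Depth limited single bins: 3.39 MTF2 reads were expected per bin, so a bin without MTF2 reads does not show absence. Thinning JARID2 to the MTF2 depth kept 93.3% of JARID2 regions. No paired analysis was possible because each factor had 1 library and no result came from a test between groups.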

Other observations

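All tests in this part were chosen only after the results they concern had been seen. Of 18 MTF2 regions of 20 kb or more, 13 had a JARID2 fold less than 2 times the MTF2 fold, although JARID2 itself reached 203-fold in the region on chromosome 9 from 3000001. On chromosome 8, 27 MTF2 regions of any width, with 362 kb in all, lay between 19681001 and 20457000, with a median of 7.32-fold in MTF2 (5.41 to 12.3) and 4.46-fold in JARID2 (0.857 to 8.99). On chromosome 7, from 64345001 to 64372000, MTF2 was 6.24-fold (5.74 to 6.78) over 27 kb while JARID2 was at 0.976-fold (0.807 to 1.17).

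Some wide JARID2 regions showed evenly spaced peaks. Of 21 regions of 25 kb or more, 5 had an autocorrelation of at least 0.5 at a fixed spacing. The widest JARID2 region, 148 kb on chromosome 6 from 114455001 to 114603000, had a spacing of 2400 bp, with JARID2 at 21.1-fold and MTF2 at 1.08-fold (0.992 to 1.17), and chromosome 4 from 88244001 to 88278000 had 2900 bp, 25.4-fold and 1.30-fold (1.097 to 1.52). In the other 3 MTF2 was raised too, to 12.1-fold on chromosome 6 from 47580001, 10.9-fold on chromosome 6 from 47666001 and 3.52-fold on chromosome 8 from 126423001. Extra copies of a repeated unit would raise both libraries alike if reads of both libraries mapped alike. The JARID2 fold was at least 8.85 times the MTF2 fold in all 5. This argues against extra copies as the whole cause only under that condition. Reads of 36 and 52 bp may map differently in repeats, which was not tested, so extra copies as the whole cause are not excluded. Extra copies as part of the cause also remain open for the 3 with raised MTF2.

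The 4 widest shared regions selected by fold may lie over the Hox clusters, which encode homeodomain regulators of body axis patterning. In the GRCm38.p6 gene table Hoxa lies on chromosome 6, Hoxb on 11, Hoxc on 15 and Hoxd on 2, and the 4 regions fall 1 on each of these. Random draws of 4 from the 366 regions that met the selection put 1 on each in a share of 0.00019. The selection was made after the widest regions had been listed, and without it wider JARID2 regions of 148, 88 and 78 kb on chromosomes 6, 8 and 11 come before all 4. Positions were not compared across builds, so this remains a hypothesis on chromosomes alone.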
